A study of Escherichia coli with 12 samples.

How the data were processed

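Purified tRNA of Escherichia coli strain CA244 was profiled at its 3′ ends in 12 libraries. Per the labels' protocols, cultures were kept in LB at 37 °C with shaking at 250 rpm, total RNA was extracted with hot phenol or TRIzol, and tRNA was purified on polyacrylamide gels. An adapter was then ligated to the 3′ end, the RNA was fragmented in alkali, a 5′ adapter was ligated, and the product was reverse transcribed and amplified by PCR. Which of the extractions was used for which library is not given in the sources used here. The labels name 5 groups: wild type in exponential phase (wt_exp, n = 3) and in stationary phase (wt_stat, n = 3), a cca knockout in both phases (cca_exp and cca_stat, n = 2 each) and an rnt knockout in exponential phase (rnt_exp, n = 2). A library is named here by its group and replicate, as in wt_exp 3. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals cover counting error only.

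The values in the deposited files are raw read counts, 1 file per library, which the authors did not normalize. Per the file headers, each count belongs to a 10-nt tail (the tRNA bases before the CCA) and to an end class: CCA, CC, C, none of these bases, or another end. The class with none of these bases is called no added base here. That name does not say whether a CCA was encoded in the gene or added later. Per the submitters' processing notes, adapters were handled with cutadapt 1.2.1. The aligner, the counting rule and the genome build are not given in the sources used here. Files held 45 rows named for E. coli, of which 41 named 1 tRNA and 4 pooled tRNAs that share a tail, called pooled tail 1 to pooled tail 4 here. A row name gives the amino acid and the anticodon as DNA, so that tRNA-Cys-GCA is the cysteine tRNA with anticodon GCA. None of these names matched the gene name table at hand (0 of 45), so no coordinates are given. Files also held 5 or 6 rows without an E. coli name, which took 22.8% (rnt_exp 2) to 57.5% (rnt_exp 1) of a library's reads and were kept out of tests and library sizes. In 5 files, 5 further end classes longer than CCA had columns of their own, and these were added to the other ends. Serial numbers in the file names fall into 3 runs, treated as library series. Series 1 holds replicate 1 of wt_exp, wt_stat, cca_exp and cca_stat, series 2 holds replicate 2 of wt_exp and wt_stat with rnt_exp 1, and series 3 holds replicate 3 of wt_exp and wt_stat with replicate 2 of cca_exp, cca_stat and rnt_exp.

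The total of reads per library ran from 3261655 (wt_stat 2) to 16717877 (cca_stat 1), and reads of E. coli rows from 1703292 (wt_stat 2) to 9526435 (wt_exp 3). At this depth the 95% Wilson interval of a library's CC share reached at most 0.0207 percentage points to either side. Replicates of a group differed far beyond counting error: a chi-square over tRNAs divided by its 43 degrees of freedom was 3942 (wt_stat 2 and 3) or more for every pair, so no libraries were merged.

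Choices in this paragraph were made before the data were examined. The odds of a complete end were tested per tRNA with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on paired columns (reads ending in CCA, all other reads), with an intercept per library and all 12 libraries in 1 fit. tRNAs under a mean of 20 reads per library were left out, which removed tRNA-Met-CAT-1-1 (0 to 12 reads per library) and left 44. The same form was used for CC ends against C or no added base. Relative abundance was tested with edgeR on all reads of a tRNA after TMM normalization. Adjusted p-values are Benjamini-Hochberg values over 44 tRNAs, called under 0.05. The share of each end class per library, pooled over tRNAs, was compared with a two-sided exact permutation test whose p is the share of arrangements with an absolute difference at least as large. Its smallest p is 0.1 for 3 against 3 or 2 against 3 libraries, 0.333 for 2 against 2, and 0.01 for cca against wild type permuted within phases, which takes the phases as independent. Thus single pairs of groups could not reach 0.05. Doubling the smaller tail instead turns the smallest p for 2 against 3 into 0.2.

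Lists of tRNAs were fixed by the base before the CCA (the discriminator) and by known classes: discriminator A, discriminator G, pyrimidine discriminator, long variable arm, tRNAs encoded in rRNA operons, readers of rare codons, and substrates of class I and class II aminoacyl-tRNA synthetases. A list was compared with all other tRNAs by camera of limma 3.58.1 on log2 odds (0.5 added to both counts) or log2 CPM, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The discriminator lists were fixed by amino acid, without arginine tRNAs and pooled tails. The tails show that 2 further tRNAs, tRNA-Arg-CCG and tRNA-Arg-TCT, have G as their last base, and these count among the other tRNAs. Tails with G as their last base took 64.3% (wt_stat 1) to 91.2% (wt_stat 3) of a library's E. coli reads. The list tests thus do not separate the discriminator from the read share of its tRNAs. Of the rare-codon readers, 5 were in the files. The rRNA operon list as fixed takes both threonine GGT tRNAs. The gene table places the gene of 1 of them outside the rRNA operons, and the names in the files do not tell which tail is whose, so at most 1 of them belongs there. No name in the files gives the initiator tRNA, a tyrosine tRNA or tRNA-Ile-CAT. They may be within the pooled tails or under other names, such as tRNA-Met-CAT-3-1, which was not checked for want of a genome sequence, so values of those may include them. The text names up to 8 tRNAs with the largest rise and up to 8 with the largest fall among those called. Where none was called it names the 3 with the largest change, and it always names tRNA-Asp-GTC, which had the most reads. For a list that is described, 2 to 4 members with the smallest p are named.

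Alternatives were DESeq2 1.42.0, limma on log2 odds with 0.5 or 5 added, the replicate number or the library series as a block, coverage minimums of 100 reads or none, other definitions of an incomplete end, other size factors, only the groups compared, each tRNA weighted alike, and leaving out each library in turn. After the data were seen, 9 were added: leaving out wt_exp 3 and rnt_exp 2 together (in the model fits and in the library shares), lists by the tail's last base, camera with the series as a block, only CC ends counted as incomplete, crossed replicate numbers as a block, camera with each library left out in turn, the rRNA operon list less each threonine GGT tRNA, and an exact permutation that moves same-numbered libraries of both phases together. Whether replicate numbers pair libraries was checked before the fits with a block were compared. Between wt_exp and wt_stat, deviations of same-numbered libraries from their group means correlated across tRNAs at 0.82, 0.70 and 0.55 for log2 odds and 0.81, 0.87 and 0.54 for log2 CPM. The replicate numbers come from the titles, and same-numbered wild-type libraries went together. In the wild type each number is also a library series, so pairing by number cannot be told apart from a shared series. Used as a block over all groups, the number joins wild-type libraries of series 2 with cca libraries of series 3. No other groups had 3 pairs. Moved as pairs over both phases, cca and wild type allow 10 arrangements, with a smallest p of 0.1.

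The fits were tested on 20 simulated tables with 10 changed tRNAs each. For the odds of a complete end in cca against wild type over both phases, 14% of 100 changes of 2-fold and 59% of 100 changes of 4-fold in the odds were recovered among 44 tRNAs, and 0.882% of 680 unchanged tRNAs were called. These were 6 false calls beside 14 and 59 true ones. For abundance in wt_stat against wt_exp, 2% of 100 changes of 2-fold and 27% of 100 of 4-fold were recovered, and 0.147% of 680 unchanged tRNAs were called. The simulated counts were drawn independently for each tRNA and library, with dispersions fitted to these data. No shift shared by the tRNAs of a library, or by the libraries of a series, was simulated. Calls on unchanged tRNAs that such shifts would cause are therefore not measured by these rates. Each SE beside an edgeR log2 change is the size of that change divided by the square root of its F statistic. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for shares and plots.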

Results

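The 3′ ends of tRNA were counted in 12 libraries from Escherichia coli strain CA244: the wild type in exponential (wt_exp, n = 3) and stationary phase (wt_stat, n = 3), a cca knockout in both phases (cca_exp and cca_stat, n = 2 each) and an rnt knockout in exponential phase (rnt_exp, n = 2). The cca gene encodes the CCA-adding enzyme, which rebuilds the terminal CCA that a tRNA needs to carry an amino acid, and rnt encodes RNase T, an exoribonuclease that trims RNA 3′ ends. Each count is a number of reads per tRNA tail and end class. In wt_exp, 94.4% ± 2.41 (SD, n = 3) of reads ended in the complete CCA, 2.15% ± 2.09 in CC, 0.240% ± 0.0723 in C and 0.134% ± 0.0840 without any base of the CCA. The largest shares of wt_exp reads belonged to tRNA-Asp-GTC (16.7% ± 3.50), tRNA-Asn-GTT (16.2% ± 5.03) and tRNA-Glu-TTC (16.0% ± 6.91). Reads of E. coli tRNAs ran from 1703292 (wt_stat 2) to 9526435 (wt_exp 3) per library. Only tRNAs were counted in the files, so the cca and rnt genes themselves were not measured here and the genotypes rest on the labels.

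The cca knockout and the wild type were compared to see how 3′ ends differ without the gene for the CCA-adding enzyme. In exponential phase, 7.21% ± 0.0691 of cca_exp reads (n = 2) ended in CC, against 2.15% ± 2.09 in wt_exp (n = 3). tRNA-Cys-GCA (tail GAACGCGCCT) had the widest gap, with 52.2% ± 0.313 CC ends in cca_exp and 8.82% ± 4.16 in wt_exp. tRNA-Gly-GCC, named after its values were seen, had 30.2% ± 1.47 against 6.81% ± 5.35, while tRNA-Asp-GTC had 2.98% ± 0.867 against 0.988% ± 0.965. For 12 of 44 tRNAs both cca_exp libraries lay above all 3 wt_exp libraries, where chance gives 10% of tRNAs, and for 0 they lay below. The tRNAs of a library can shift together, so here and below such counts are not independent trials. A count above the chance share can arise from a shift of whole libraries.

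The exact permutation test gave p = 0.2 for the CC share of cca_exp against wt_exp, and p = 0.2 for the complete CCA, which stood at 88.5% ± 0.257 in cca_exp (n = 2). Ends in C made up 0.717% ± 0.0677 of cca_exp reads and 0.240% ± 0.0723 of wt_exp reads (exact permutation p = 0.1, the smallest possible). Within library series, CC shares of cca_exp and wt_exp were 7.26% and 0.932% in series 1 and 7.16% and 4.56% in series 3. For the odds of a complete end per tRNA, edgeR called 0 of 44 tRNAs and found 2 at an unadjusted p under 0.05. limma called 0, and DESeq2 called 1, tRNA-Gln-TTG. With the replicate number as a block edgeR called 2, tRNA-Gln-TTG (−2.03, SE 0.57) and tRNA-Leu-GAG (−2.28, SE 0.69), at adjusted p = 0.0444 each. In the fit without a block the log2 change in the odds was −2.24 (SE 1.003, adjusted p = 0.570) for tRNA-Cys-GCA, −1.81 (SE 0.78, adjusted p = 0.570) for tRNA-Gln-TTG and −1.79 (SE 1.02, adjusted p = 0.749) for tRNA-Thr-GGT-1-1. For tRNA-Asp-GTC it was −0.74 (SE 0.66, adjusted p = 0.882). The estimate was negative for 40 of 44 tRNAs. With the library series as a term edgeR called 1 tRNA, tRNA-Cys-GCA at −2.75 (SE 0.77, adjusted p = 0.0181). None of the 8 lists stood apart from the other tRNAs (camera, adjusted p = 0.577 to 0.948).

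In stationary phase, 4.75% ± 1.35 of cca_stat reads (n = 2) ended in CC, against 0.916% ± 0.338 in wt_stat (n = 3). Complete ends fell in all 3 threonine tRNAs tested under their own names. For tRNA-Thr-GGT-1-1 (tail CCTATCAGCA) the complete end made up 56.2% ± 7.45 of reads in cca_stat and 92.2% ± 5.04 in wt_stat, for tRNA-Thr-GGT-2-1 (tail GGTATCAGCA) 55.8% ± 8.93 and 91.1% ± 4.38, and for tRNA-Thr-TGT (tail GTAGTCGGCA) 72.4% ± 6.12 and 94.6% ± 4.08. Complete ends also fell in tRNA-Leu-GAG (tail GTCCTCGGTA), from 93.9% ± 5.24 in wt_stat to 68.9% ± 2.68 in cca_stat, and in pooled tail 2 (CCCCCTCGCA), from 87.7% ± 7.06 to 59.2% ± 0.547. For 26 of 44 tRNAs both cca_stat libraries had a higher CC share than all 3 wt_stat libraries, where chance gives 10%, and for 0 a lower one. Again the 44 tRNAs are not independent.

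These 5 tRNAs were the ones edgeR called of 44 in stationary phase (adjusted p = 0.0246 each), with log2 changes in the odds of −3.47 (SE 1.06), −3.16 (SE 1.01), −3.03 (SE 0.99), −3.17 (SE 0.92) and −2.51 (SE 0.83) in the order given. The edgeR fits of end classes pool the estimate of spread over tRNAs, which can shift together within a library. Their SEs and p-values may therefore be too small, here and in the other comparisons. For tRNA-Asp-GTC the log2 change was −0.33 (SE 0.68, adjusted p = 0.864). Of the 20 tRNAs with discriminator A, 4 fell: tRNA-Leu-GAG and the 3 threonine tRNAs. Adjusted over the list alone 5 fell, tRNA-Leu-TAA (−2.58) being the fifth. The median of this list was −1.29 against −0.25 in the other tRNAs (camera, adjusted p = 0.0108), and the median of the 11 tRNAs of the fixed list with discriminator G, of which 0 were called over all tRNAs or adjusted over the list alone, was −0.02 against −1.14 (camera, adjusted p = 0.00380). Both calls were lost with an estimated correlation (adjusted p = 0.989 with an estimated correlation for each). Both were also lost without wt_stat 1 (camera, adjusted p = 0.140 for A and 0.133 for G) and without cca_stat 1 (0.417 and 0.261), in fits of the lists with each library left out that were chosen after seeing the data. Taken by the tail's last base, which puts 2 arginine tRNAs with G in as well (13 tRNAs, and 26 with A), both passed (camera, adjusted p = 0.000207 for A and 5.00e-05 for G), a choice also made after seeing the data. Of the list with discriminator G, tRNA-Gln-TTG had −0.64 and tRNA-Ser-TGA 0.35. The other 6 lists had adjusted p = 0.909 to 0.978 in camera, although 2 of 7 tRNAs of the rRNA operon list (both threonine GGT tRNAs, of which at most 1 belongs there), 3 of 20 class II substrates, 1 of 19 class I substrates and 1 of 9 with a long variable arm were among those called. Adjusted over the list alone these counts were 2, 3, 1 and 2, and they were 0 for pyrimidine discriminators and rare-codon readers on either basis. Less tRNA-Thr-GGT-1-1 or less tRNA-Thr-GGT-2-1, a choice made after seeing the data, the rRNA operon list had adjusted p = 0.909 or 0.956 in camera, and it passed in none of the comparisons (lowest adjusted p = 0.210).

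The count of 5 rested on single libraries: it was 0 without wt_stat 1, without cca_stat 1 or without cca_stat 2, and 2 without wt_stat 2 (tRNA-Thr-GGT-1-1 and tRNA-Thr-GGT-2-1). It was also 0 with only these groups in the fit or with only CC ends counted as incomplete, 14 with the library series as a term and 15 with the replicate number as a block. The CC share differed at p = 0.1 in the exact permutation test (n = 2 and 3), the smallest it allows. Within library series, CC shares of cca_stat and wt_stat were 3.80% and 0.543% in series 1 and 5.70% and 1.202% in series 3. Ends in C were at 0.556% ± 0.165 in cca_stat and 0.194% ± 0.0995 in wt_stat, and ends without an added base at 0.488% ± 0.245 and 0.103% ± 0.0436 (exact permutation p = 0.1 for each). The latter difference of 0.384 points was 0.211 without cca_stat 2 and 0.558 without cca_stat 1.

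**Figure D1:**
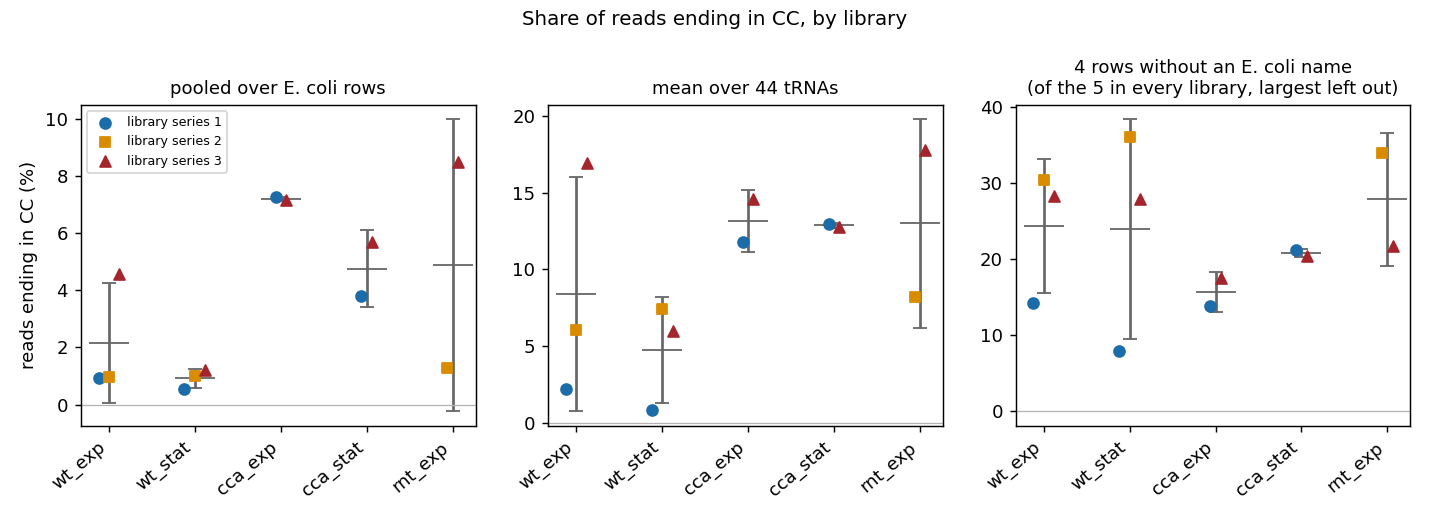
Percent of reads ending in CC per library (points, coloured by library series), with group means (horizontal lines) and SDs (bars), pooled over E. coli tRNAs (left), as the mean over 44 tRNAs (middle) and over 4 of the 5 rows without an E. coli name that every library holds, the largest left out (right). In the left panel cca_exp lies at 7.16% and 7.26%, above every wt_exp library (highest wt_exp 3 at 4.56%), while in the middle panel wt_exp 3 at 17.0% lies above both cca_exp libraries (11.8% and 14.6%).

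Over both phases, complete ends fell in 6 of 44 tRNAs of the cca knockout and rose in 0. They were tRNA-Thr-GGT-1-1 (log2 change in the odds −2.63, SE 0.73, adjusted p = 0.00884 in edgeR), tRNA-Leu-GAG (−2.36, SE 0.64, adjusted p = 0.00884), tRNA-Thr-GGT-2-1 (−2.33, SE 0.70, adjusted p = 0.0151), tRNA-Cys-GCA (−2.22, SE 0.71, adjusted p = 0.0167), tRNA-Thr-TGT (−1.93, SE 0.69, adjusted p = 0.0381) and pooled tail 2 (−1.87, SE 0.58, adjusted p = 0.0167). tRNA-Cys-GCA carried CC on 52.2% ± 0.313 of reads in cca_exp and 43.7% ± 5.83 in cca_stat, against 8.82% ± 4.16 in wt_exp and 4.96% ± 1.61 in wt_stat. Its reads numbered 1964 to 64858 per library. For tRNA-Asp-GTC the log2 change was −0.54 (SE 0.47, adjusted p = 0.629). The fit takes the libraries of both phases as independent, while same-numbered wild-type libraries deviated alike. SEs and p-values over both phases may therefore be too small.

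For 12 of 44 tRNAs, which are not independent, every cca library lay above every wild-type library of its phase in CC share. Chance gives 1% if the phases are independent. Those 12, named after their values were seen, were the tRNAs Asp-GTC, Cys-GCA, Gln-CTG, Gln-TTG, Gly-CCC, Gly-GCC, Gly-TCC, Leu-GAG, Thr-GGT-1-1, Thr-GGT-2-1 and Thr-TGT, and pooled tail 3. Only tRNA-Cys-GCA and tRNA-Leu-GAG, also named after the fact, had CC shares in all 4 cca libraries above all wild-type and rnt libraries. Chance gives 0.202% if all libraries are exchangeable across phases and series. Same-numbered wild-type libraries deviated alike, so that this share may be too low. The CC share pooled over tRNAs was higher in the cca knockout by 4.45 percentage points over both phases (exact permutation within phases p = 0.01, the smallest possible if the phases are independent), and every cca library lay above every wild-type library of its phase. Adjusted over 35 such exact permutation tests, the p was 0.175. Ends in C were higher by 0.420 points (exact permutation p = 0.01, adjusted p = 0.175), ends without an added base by 0.245 points (p = 0.02, adjusted p = 0.233, and 0.159 points without cca_stat 2), and complete ends were lower, at a difference of −4.89 points (p = 0.03, adjusted p = 0.263). Other ends differed by −0.221 points (exact permutation p = 0.77). Moved as same-numbered pairs of both phases, a choice made after seeing the data, the libraries allow 10 arrangements and no p under 0.1: the exact permutation p was 0.1 for CC, C and no added base, 0.2 for complete ends and 0.8 for other ends. With each tRNA weighted alike, the CC difference was 6.46 points (exact permutation within phases p = 0.06) and that of complete ends −6.46 points (p = 0.12), so that neither passed 0.05.

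Of the pyrimidine-discriminator tRNAs, 1 of 5 fell (tRNA-Cys-GCA), or 2 adjusted over the list alone, with tRNA-Gly-GCC at −1.73 in second place. Of those with discriminator A, 4 of 20 fell (the 3 threonine tRNAs and tRNA-Leu-GAG), or 5 adjusted over the list alone with tRNA-Leu-TAG at −1.92. For the long variable arm the counts were 1 and 2, for rRNA operons 2 and 2, for class II substrates 3 and 4, for class I substrates 2 and 2, and for discriminator G and rare-codon readers 0 and 0. No list passed camera (adjusted p = 0.285 for discriminator G, 0.418 for discriminator A, 0.869 for the other 6). Discriminator G passed without wt_stat 2 (adjusted p = 0.0258) or without cca_exp 1 (0.0360). With the library series as a term, discriminator G lay above the other tRNAs (adjusted p = 0.00302) and discriminator A was at 0.0652. The count of 6 was 0 without cca_exp 1, without cca_exp 2 or without cca_stat 1. It was 2 without wt_exp 1 (tRNA-Leu-GAG and tRNA-Thr-GGT-1-1) and 10 without wt_exp 3. It was 3 without wt_exp 2 (tRNA-Cys-GCA and both threonine GGT tRNAs) and 3 without cca_stat 2 (tRNA-Leu-GAG and both threonine GGT tRNAs). It was 18 with the replicate number as a block, which crosses the library series. With the library series as a term it was 14, including all 6, with tRNA-Cys-GCA at −2.73 (SE 0.56, adjusted p = 8.06e-05).

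**Figure D2:**
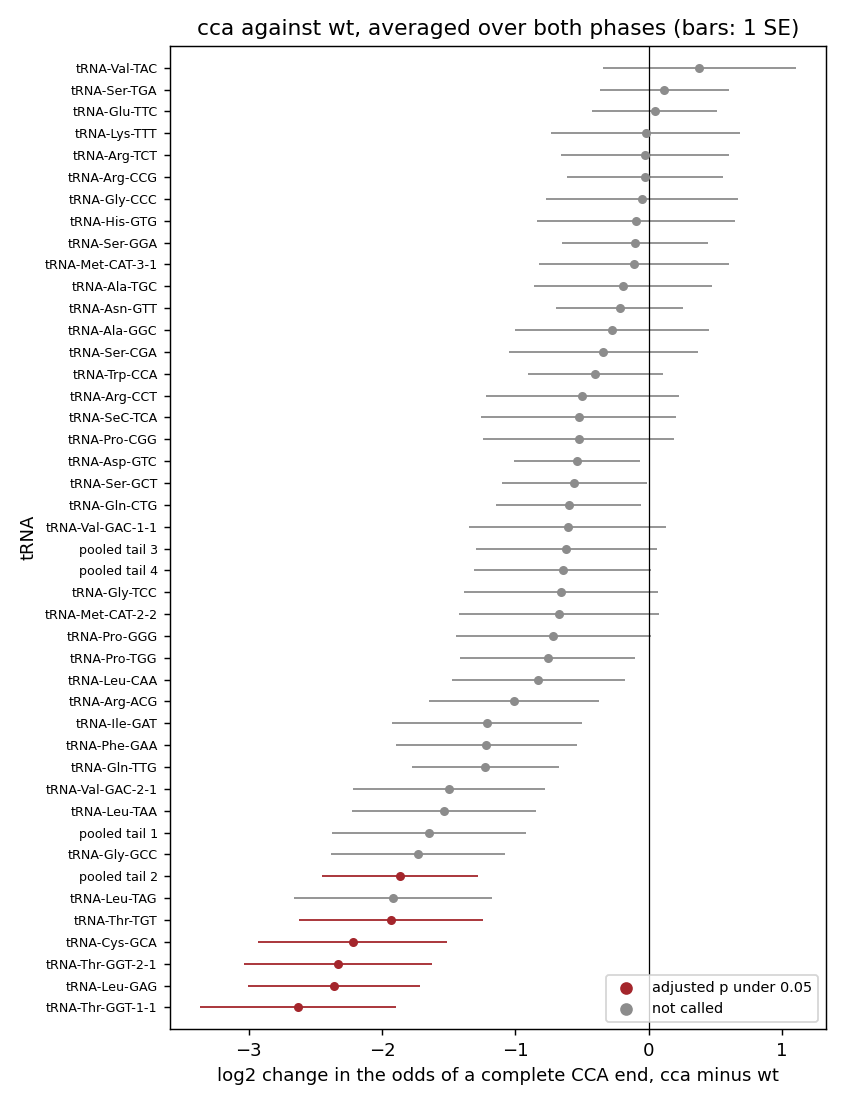
Log2 change in the odds of a complete CCA end per tRNA, cca against wild type averaged over both phases (edgeR, points with bars of 1 SE), ordered by size. The SE is derived from the F statistic. The 6 called tRNAs (red, adjusted p under 0.05) lie between −2.63 and −1.87, and 41 of the 44 estimates are negative.

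Among the incomplete ends, CC was set against C or no added base. In the cca knockout over both phases edgeR called 0 of 44 tRNAs, with 1 at an unadjusted p under 0.05, and limma and DESeq2 called 0. The log2 change in the odds of CC was 2.82 (SE 1.07, adjusted p = 0.383) for tRNA-Cys-GCA, 1.79 (SE 1.05, adjusted p = 0.960) for tRNA-Gly-GCC, 1.68 (SE 1.07, adjusted p = 0.960) for tRNA-Thr-TGT and 1.05 (SE 1.05, adjusted p = 0.960) for tRNA-Asp-GTC. The call of tRNA-Cys-GCA turned on the fit. It was called with the replicate number as a block (3.24, SE 0.91, adjusted p = 0.0206) and without wt_exp 3 and rnt_exp 2, an alternative chosen after seeing the data (3.02, SE 0.89, adjusted p = 0.0372), but not with the library series as a term (1.97, SE 0.96, adjusted p = 0.988).

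**Figure D3:**
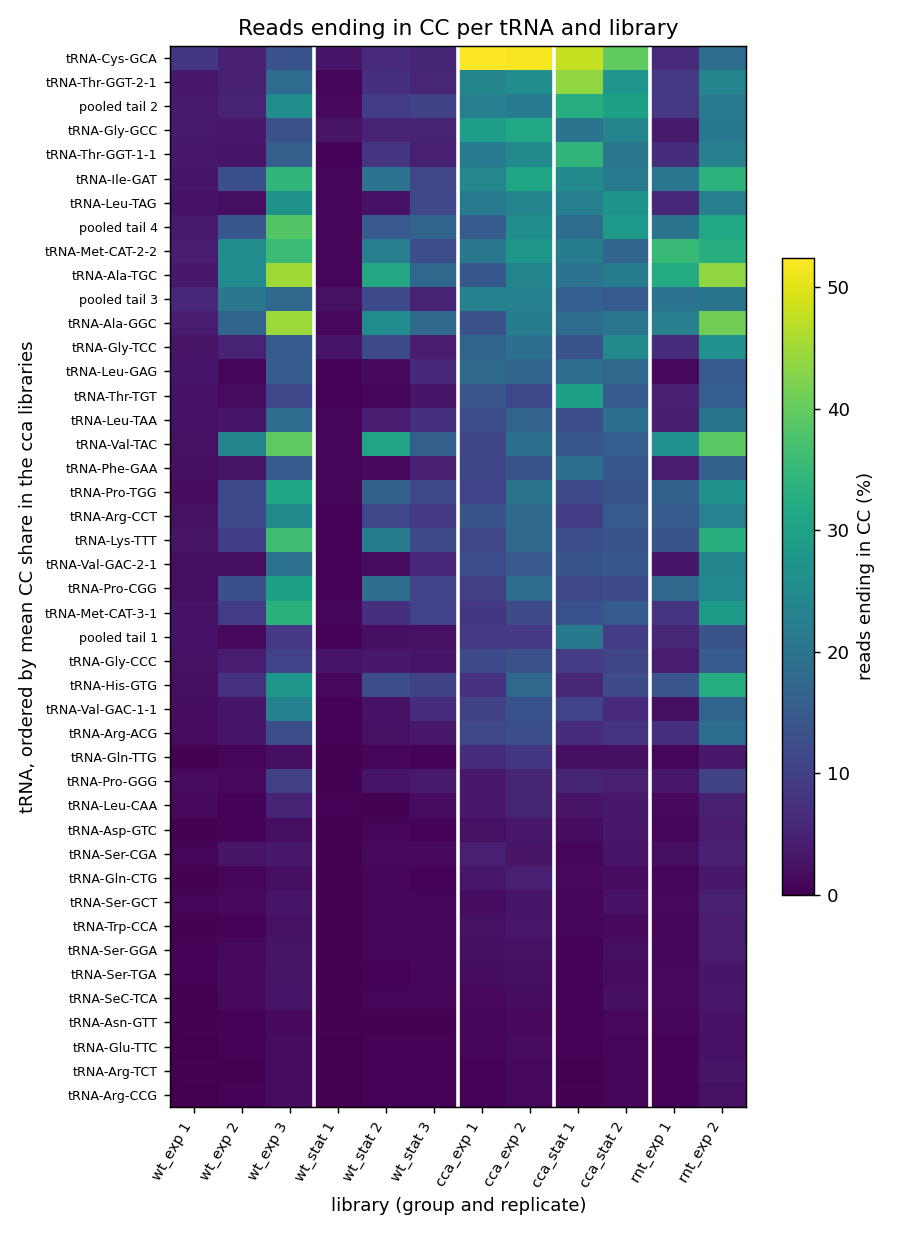
Percent of reads ending in CC for 44 tRNAs (vertical, ordered by the mean over the cca libraries) in 12 libraries (horizontal, groups parted by white lines), on a linear colour scale. tRNA-Cys-GCA stands out in the cca libraries with group means of 52.2% (cca_exp) and 43.7% (cca_stat), and wt_exp 3 and rnt_exp 2 are brighter than the other libraries of their groups.

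The rnt knockout was compared with the wild type to see how 3′ ends differ without the gene for RNase T. CC ends made up 4.88% ± 5.10 of reads in rnt_exp (n = 2) and 2.15% ± 2.09 in wt_exp (n = 3), and complete ends 91.1% ± 4.31 and 94.4% ± 2.41. For tRNA-Met-CAT-3-1 the complete end was at 41.4% ± 23.8 in rnt_exp and 68.4% ± 19.5 in wt_exp, and for tRNA-Lys-TTT at 56.3% ± 5.36 and 76.6% ± 17.2. Of 44 tRNAs, 0 had CC shares in both rnt_exp libraries above or below all wt_exp libraries, where chance gives 10% in each direction.

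The exact permutation test gave p = 0.5 for CC and p = 0.4 for the complete end (n = 2 and 3). Within series, CC shares of rnt_exp and wt_exp were 1.27% and 0.954% in series 2 and 8.49% and 4.56% in series 3. The CC difference of 2.73 points was −0.883 without rnt_exp 2 and 6.34 without rnt_exp 1. edgeR called 0 of 44 tRNAs, with 0 at an unadjusted p under 0.05, and limma and DESeq2 called 0. The log2 change in the odds of a complete end was −1.87 (SE 1.06) for tRNA-Met-CAT-3-1, −1.71 (SE 1.02) for tRNA-Thr-GGT-1-1, −1.63 (SE 1.01) for tRNA-Lys-TTT and −0.90 (SE 0.66) for tRNA-Asp-GTC, all at adjusted p = 0.810, and was negative for all 44 tRNAs. The median was −1.05 for discriminator A against −0.48 in other tRNAs (camera, adjusted p = 0.00163), −0.30 for discriminator G against −0.82 (adjusted p = 0.00238) and −0.39 for the long variable arm against −0.82 (adjusted p = 0.00736), with 0 members called in any list, also adjusted over the list alone. For these 3 lists the adjusted p = 0.511 with an estimated correlation. All 3 lost their calls without wt_exp 1 (camera, adjusted p = 0.275, 0.770 and 0.275) and without rnt_exp 1 (0.143, 0.712 and 0.864), and the long variable arm also without wt_exp 3 (0.0618). With the library series as a term only discriminator A kept a camera call (adjusted p = 0.0171, against 0.117 and 0.140). The other 5 lists had adjusted p = 0.277 to 0.884. Among incomplete ends edgeR called 0 of 44 tRNAs in rnt_exp against wt_exp, with 0 at an unadjusted p under 0.05, and limma and DESeq2 called 0. The log2 change in the odds of CC was 1.997 (SE 2.01) for tRNA-Leu-TAA, 1.87 (SE 1.71) for pooled tail 1 and 1.81 (SE 1.66) for tRNA-Gly-TCC (adjusted p = 0.784 each), and 0.31 (SE 1.52, adjusted p = 0.837) for tRNA-Asp-GTC.

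Between the knockouts in exponential phase, tRNA-Cys-GCA ended in CC in 12.3% ± 8.67 of rnt_exp reads and 52.2% ± 0.313 of cca_exp reads (n = 2 each), and tRNA-Val-TAC in 32.6% ± 9.06 and 15.2% ± 5.83. Both rnt_exp libraries lay above both cca_exp libraries for 4 of 44 tRNAs and below for 5, where chance gives 16.7% in each direction. CC shares over all tRNAs were 4.88% ± 5.10 and 7.21% ± 0.0691 (exact permutation p = 1), and in series 3, the only series with both, 8.49% and 7.16%, so that the order was the opposite. The CC difference was −5.94 points without rnt_exp 2 and 1.28 without rnt_exp 1. edgeR called 0 of 44 tRNAs, with 0 at an unadjusted p under 0.05, and limma and DESeq2 called 0. The log2 change in the odds of a complete end (rnt_exp against cca_exp) was −1.97 (SE 1.08) for tRNA-Val-TAC, −1.84 (SE 1.11) for tRNA-Met-CAT-3-1, −1.67 (SE 1.07) for tRNA-Lys-TTT and −0.15 (SE 0.72) for tRNA-Asp-GTC (adjusted p = 0.967 each). With only these groups in the fit, 1 tRNA was called, tRNA-Met-CAT-3-1 at −1.82 (SE 0.48, adjusted p = 0.0133). Discriminator A had a median of −0.61 against 0.03 (camera, adjusted p = 0.0414, adjusted p = 0.957 with an estimated correlation, and 0.171 with the library series as a term). It lost its call without cca_exp 1 (adjusted p = 0.329) or without rnt_exp 1 (0.182). Discriminator G and the long variable arm passed without cca_exp 2 (adjusted p = 0.0184 and 0.0156) or without rnt_exp 2 (0.0236 for both). The other 7 lists had adjusted p = 0.0688 to 0.914.

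Growth phases were compared within the wild type and within the cca knockout. In the wild type, CC ends made up 0.916% ± 0.338 of reads in wt_stat and 2.15% ± 2.09 in wt_exp (n = 3 each), and complete ends 95.6% ± 1.81 and 94.4% ± 2.41. For tRNA-Thr-TGT complete ends were at 94.6% ± 4.08 in wt_stat and 85.7% ± 8.32 in wt_exp, and for tRNA-Leu-TAA at 91.4% ± 5.72 and 81.6% ± 9.27. Of 44 tRNAs, 0 had CC shares in all wt_stat libraries above or below all wt_exp libraries, where chance gives 5% in each direction. The exact permutation test gave p = 0.6 for CC and for the complete end, and CC shares of wt_stat and wt_exp were 0.543% and 0.932% in series 1, 1.004% and 0.954% in series 2 and 1.202% and 4.56% in series 3, so that series 2 went the other way. The difference in complete ends turned from 1.16 points to −0.168 without wt_exp 3. edgeR called 0 of 44 tRNAs, with 0 at an unadjusted p under 0.05, and limma and DESeq2 called 0. The log2 change in the odds of a complete end was 1.70 (SE 0.89) for tRNA-Thr-TGT, 1.41 (SE 0.89) for tRNA-Leu-TAA and 1.25 (SE 0.98) for tRNA-Val-TAC (adjusted p = 0.754 each), and 0.21 (SE 0.60, adjusted p = 0.862) for tRNA-Asp-GTC. It was positive for 43 of 44 tRNAs. Discriminator G had a median of 0.33 against 0.81 in the others (camera, adjusted p = 0.00228, adjusted p = 0.982 with an estimated correlation), with tRNA-Ser-GCT at 0.56 and tRNA-SeC-TCA, the selenocysteine tRNA, at 0.69. It lost its call without wt_exp 2 (camera, adjusted p = 0.270), without wt_exp 3 (0.294) or without wt_stat 1 (0.770). Discriminator A passed without wt_exp 1 (adjusted p = 0.00361) or without wt_stat 2 (0.0223). The other 7 lists had adjusted p = 0.0847 to 0.959.

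In the cca knockout, CC ends made up 4.75% ± 1.35 of reads in cca_stat and 7.21% ± 0.0691 in cca_exp (n = 2 each, exact permutation p = 0.333, the smallest possible). In series 1 the shares were 3.80% and 7.26%, and in series 3 they were 5.70% and 7.16%. For tRNA-Gln-TTG CC ends were at 2.12% ± 0.0733 in cca_stat and 7.55% ± 1.23 in cca_exp, and for tRNA-Thr-GGT-2-1 at 35.6% ± 11.3 and 24.8% ± 1.35. Both cca_stat libraries lay above both cca_exp libraries in CC share for 6 of 44 tRNAs and below for 11, where chance gives 16.7%. edgeR called 0 of 44 tRNAs, with 0 at an unadjusted p under 0.05, and limma and DESeq2 called 0. The log2 change in the odds of a complete end was 1.74 (SE 1.11) for tRNA-Ser-CGA, 1.57 (SE 0.85) for tRNA-Ser-GCT, 1.26 (SE 0.85) for tRNA-Gln-TTG and 0.62 (SE 0.73) for tRNA-Asp-GTC (adjusted p = 0.991 each). Discriminator A had a median of −0.15 against 0.76 (camera, adjusted p = 1.95e-05) and discriminator G of 0.91 against −0.06 (adjusted p = 0.000179), both at adjusted p = 0.449 with an estimated correlation. Discriminator G lost its call without cca_stat 1 (adjusted p = 0.0667), while discriminator A kept it with any library left out. The other 6 lists had adjusted p = 0.476 to 0.756.

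Whether the phases differ in another way in the cca knockout than in the wild type was tested as an interaction. edgeR called 0 of 44 tRNAs, with 0 at an unadjusted p under 0.05, and limma and DESeq2 called 0. The log2 difference was −2.20 (SE 1.37) for tRNA-Thr-TGT, −2.08 (SE 1.37) for tRNA-Leu-TAA and −1.79 (SE 1.45) for pooled tail 1 (adjusted p = 0.997 each), and 0.41 (SE 0.95, adjusted p = 0.9998) for tRNA-Asp-GTC. Discriminator A had a median of −1.04 against 0.23 (camera, adjusted p = 2.66e-05) and discriminator G of 0.59 against −0.85 (adjusted p = 1.62e-05), both at adjusted p = 0.415 with an estimated correlation. They kept their calls with any library left out. As in the other list tests, the discriminator was not separated from the read share of its tRNAs. The other 6 lists had adjusted p = 0.602 to 0.833.

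Relative abundance of tRNAs was compared between the same groups. tRNA-Asn-GTT took 8.51% ± 1.87 of reads in cca_exp (n = 2) and 16.2% ± 5.03 in wt_exp (n = 3), and tRNA-Cys-GCA 0.837% ± 0.217 and 0.213% ± 0.0915. The tRNAs with discriminator G were lower than the others in cca_exp against wt_exp, with a median log2 change of −1.002 against 0.56 (camera, adjusted p = 7.15e-10, and adjusted p = 0.0373 with an estimated correlation), among them tRNA-Asn-GTT (−1.81) and tRNA-Glu-TTC (−1.14). The long variable arm, at −0.98 against 0.52 (adjusted p = 0.00169), and discriminator A, at 0.43 against −0.75 (adjusted p = 0.0293), lost their calls with an estimated correlation (adjusted p = 0.160 and adjusted p = 0.301 with an estimated correlation). With the library series as a term discriminator G kept its call (adjusted p = 2.99e-08) and so did the long variable arm (0.0127), while discriminator A did not (0.0579). Of the 11 tRNAs of the fixed list with discriminator G, 5 (4 serine tRNAs and tRNA-SeC-TCA, all among the 9 with a long variable arm and named after their values were seen) were low in cca_exp 1, at log2 ratios to wt_exp 1 of −1.29 (tRNA-Ser-TGA) to −6.12 (tRNA-Ser-GCT), but not in cca_exp 2, at −0.06 (tRNA-SeC-TCA) to 0.97 (tRNA-Ser-CGA) over wt_exp 3. Without cca_exp 1 discriminator G kept its call at a smaller difference (−0.34 against 0.50, adjusted p = 0.00157 in camera). The long variable arm (0.15 against 0.39, adjusted p = 0.859) and discriminator A (0.39 against 0.08, adjusted p = 0.668) lost theirs. The share of reads with a G before the CCA ranged from 64.3% (wt_stat 1) to 91.2% (wt_stat 3) between libraries of 1 group. Scaling by library totals in place of TMM moved the median of all tRNAs by up to 0.64 on the log2 scale (cca_exp against wt_exp), and the median of discriminator G was then −0.26, still under that of all tRNAs.

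edgeR called 0 of 44 tRNAs in abundance in each of the 7 comparisons, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. In cca_exp against wt_exp the log2 changes of tRNA-Asn-GTT (−1.81, SE 0.90), tRNA-Arg-CCT (1.34, SE 0.64), tRNA-Cys-GCA (1.29, SE 0.70) and tRNA-Asp-GTC (−0.70, SE 0.75) had adjusted p = 0.694. Without cca_exp 2, leaving cca_exp 1 alone, 2 serine tRNAs named after their values were seen were called lower: tRNA-Ser-GCT (−6.59, SE 1.05, adjusted p = 0.00245) and tRNA-Ser-CGA (−4.50, SE 1.03, adjusted p = 0.0238). In cca_stat against wt_stat the largest changes were those of tRNA-SeC-TCA (−1.34, SE 1.49), pooled tail 3 (1.07, SE 0.87) and tRNA-Asn-GTT (−0.88, SE 0.86), with tRNA-Asp-GTC at −0.25 (SE 0.74), all at adjusted p = 0.980. The change of tRNA-SeC-TCA was −0.15 without cca_stat 1 and −5.44 without cca_stat 2. There discriminator G had a median of −0.25 against 0.26 and the long variable arm of −0.35 against 0.26 (camera, adjusted p = 0.0172 for both). They had adjusted p = 0.712 and adjusted p = 0.671 with an estimated correlation, and 0.921 and 0.758 with the library series as a term. Discriminator G lost its call without wt_stat 2 (camera, adjusted p = 0.489), without wt_stat 3 (0.476) or without cca_stat 2 (0.314), and the long variable arm without wt_stat 1 (0.195), without wt_stat 2 (0.180) or without cca_stat 1 (0.762). Scaled by library totals, the median of discriminator G turned to 0.16. That of all tRNAs moved too, from −0.17 to 0.17, so this turn says nothing on the list against the others.

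In rnt_exp against wt_exp the largest changes in abundance were those of pooled tail 1 (0.85, SE 0.67), tRNA-Ala-TGC (−0.83, SE 1.05) and tRNA-Leu-TAG (−0.81, SE 0.59), with tRNA-Asp-GTC at −0.71 (SE 0.75), all at adjusted p = 0.986 in edgeR. No list passed (camera, adjusted p = 0.326 to 0.948), and with the library series as a term discriminator G lay lower (adjusted p = 1.72e-05) and discriminator A higher (adjusted p = 0.0297). Discriminator G was called lower without wt_exp 1 (adjusted p = 0.000138) or without rnt_exp 1 (7.98e-07) and higher without rnt_exp 2 (0.0360), where the long variable arm was called higher too (0.0360). In rnt_exp against cca_exp they were pooled tail 3 (−1.78, SE 0.995), tRNA-Leu-CAA (1.74, SE 1.05) and tRNA-Asn-GTT (1.59, SE 0.94) at adjusted p = 0.770, with tRNA-Asp-GTC at −0.01 (SE 0.80, adjusted p = 0.986). Discriminator G and the long variable arm both had a median of 0.97, against −0.48 and −0.46 (camera, adjusted p = 9.78e-05 and 0.000348). They had adjusted p = 0.201 and adjusted p = 0.197 with an estimated correlation, and 0.0570 for both with the library series as a term. Both lost their calls without cca_exp 1: discriminator G stood at 0.22 against −0.53 (adjusted p = 0.134) and the long variable arm at −0.22 against −0.33 (0.638). Discriminator G lost its call also without rnt_exp 1 (0.502), and discriminator A, not called with all libraries, was called without cca_exp 2 (0.0341). Without cca_exp 2, tRNA-Ser-GCT (6.51) and tRNA-Ser-CGA (4.04) were called higher in rnt_exp than in cca_exp 1.

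Between phases of the wild type the largest changes in abundance were those of tRNA-Leu-TAA (1.51, SE 0.72), tRNA-Gly-CCC (1.05, SE 0.58) and pooled tail 4 (1.03, SE 0.86), with tRNA-Asp-GTC at −0.22 (SE 0.66), all at adjusted p = 0.987 in edgeR, and no list passed (camera, adjusted p = 0.274 to 0.937). In cca_stat against cca_exp they were tRNA-Ser-CGA (1.43, SE 0.96), tRNA-Ser-TGA (1.34, SE 0.84) and tRNA-Leu-CAA (1.27, SE 1.04), with tRNA-Asp-GTC at 0.23 (SE 0.80), all at adjusted p = 0.982. Discriminator G was at 0.38 against −0.31 (camera, adjusted p = 0.000144), the long variable arm at 0.58 against −0.18 (adjusted p = 0.000229) and discriminator A at −0.50 against 0.11 (adjusted p = 0.00184), each at adjusted p = 0.146 with an estimated correlation. All 3 lost their calls without cca_exp 1, at 0.21 against −0.10, −0.19 against 0.01 and −0.19 against 0.15 (adjusted p = 0.784 each), and the long variable arm also without cca_stat 2 (0.169). In the interaction of phase and genotype the largest were pooled tail 4 (−1.46, SE 1.35), tRNA-Pro-TGG (−1.27, SE 1.22) and tRNA-Ser-CGA (1.18, SE 1.22), with tRNA-Asp-GTC at 0.45 (SE 1.04), all at adjusted p = 0.955. Discriminator G was at 0.61 against −0.24 (camera, adjusted p = 1.30e-07), discriminator A at −0.32 against 0.40 (adjusted p = 0.0226) and the long variable arm at 0.13 against −0.22 (adjusted p = 0.0446). They had adjusted p = 0.102, adjusted p = 0.350 and adjusted p = 0.388 with an estimated correlation, and the long variable arm was at 0.0720 with the library series as a term. Its median turned to −0.03 with scaling by library totals, but that of all tRNAs went from −0.18 to −0.65, so the list still lay above it. All 3 were lost without cca_exp 1, at 0.31 against 0.06 (adjusted p = 0.577), 0.09 against 0.16 (0.923) and −0.02 against 0.11 (0.248), and without wt_stat 1 (0.0507, 0.293 and 0.260). Discriminator A and the long variable arm were also lost without wt_exp 2 (0.206 and 0.476) or without cca_stat 2 (0.161 and 0.742), and the long variable arm without wt_stat 3 (0.250) or without rnt_exp 2 (0.0554). Without cca_exp 2, tRNA-Ser-GCT and tRNA-Ser-CGA were called higher in cca_stat than in cca_exp 1 (6.52 and 4.75) and in the interaction (6.03 and 4.71). In these abundance comparisons, lists not given by name had adjusted p = 0.0950 or more, and 0 members of any list were called, also adjusted over the list alone.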

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

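In this part, the test of noise between libraries was chosen before its result was seen, and the other tests of explanations and the counts over other splits after. Between-group differences in the phase effect drew attention for lists of tRNAs, by a test of the interaction in camera. For the odds of a complete end, discriminator A went lower from exponential to stationary phase in the cca knockout relative to the wild type (adjusted p = 2.66e-05, adjusted p = 0.415 with an estimated correlation), and discriminator G went higher (adjusted p = 1.62e-05, adjusted p = 0.415 with an estimated correlation). For abundance the interaction was called for discriminator A (adjusted p = 0.0226, adjusted p = 0.350 with an estimated correlation), discriminator G (adjusted p = 1.30e-07, adjusted p = 0.102 with an estimated correlation) and the long variable arm (adjusted p = 0.0446, adjusted p = 0.388 with an estimated correlation), and all 3 were lost without cca_exp 1 (camera, adjusted p = 0.923, 0.577 and 0.248). No single tRNA was called in either interaction by edgeR (0 of 44, with 0 at an unadjusted p under 0.05) or by DESeq2.

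Some signals lay in data outside the comparisons. The 5 further end classes longer than CCA stood at 534 CPM of E. coli reads in cca_exp 2 (95% Wilson interval 517 to 551) and 367 CPM in wt_exp 3 (355 to 379), the wild-type library of the same phase and series. In rnt_exp 2 they were at 81.5, in cca_stat 2 at 28.7 and in wt_stat 3 at 23.2 CPM. Rows without an E. coli name took 57.5% of the reads of rnt_exp 1, against at most 55.4% in wt_exp (wt_exp 2, of the same series). The cause was not tested for either.

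The CC change in the cca knockout differed between tRNAs, with the widest gap in exponential phase in tRNA-Cys-GCA. It was not a rise in all of them. The mean CC share over tRNAs was 14.6% in cca_exp 2 and 17.0% in wt_exp 3, so some tRNAs fell in series 3. If noise between libraries made the order of tRNAs by this change, the change in series 1 and the change in series 3 would be unrelated across the 44 tRNAs. Spearman's correlation between them was 0.549 in exponential and 0.149 in stationary phase, so noise between libraries cannot be told apart from a real order, since the phases gave different answers. Little room to rise in tRNAs with many CC ends cannot be told apart from other causes either: the CC share of wt_exp 2, a library outside both series, correlated with the change in exponential phase at 0.116 in series 1 and −0.394 in series 3. A need for the enzyme that differs between tRNAs stays a hypothesis.

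CC shares of wt_exp 3 (4.56%) and rnt_exp 2 (8.49%) lay above the other libraries of their groups, and both libraries belong to series 3. Loss of the last base at a step shared by all RNA in the library predicts a rise in the rows without an E. coli name as well, and these went both ways. Their CC shares in wt_exp 3 had a median ratio of 1.34 to wt_exp 1 (0.634 to 2.23 over 5 rows) and 0.991 to wt_exp 2 (0.5496 to 1.29), while E. coli tRNAs were at 4.90 and 4.78. In rnt_exp 2 the median ratio to rnt_exp 1 was 0.5997 (0.469 to 2.37), with E. coli tRNAs at 6.70. The ratio of 2.37 was that of the row named Gln1h, which had the fewest reads (1149 in rnt_exp 2), and the other rows fell. Relative to wt_stat 3, of the same series but another group, the medians were 1.01 in wt_exp 3 (0.979 to 1.03) and 0.835 in rnt_exp 2 (0.689 to 1.62), with E. coli tRNAs at 3.80 and 7.06. With 5 rows that differ this much between libraries of a group, the loss cannot be told apart from other causes. With the same tRNA weights in each library, 107% of the difference was left in wt_exp 3 (3.62 points before, 3.87 after), which argues against the makeup of the tRNA pool. In rnt_exp 2, 59.1% was left (7.22 points before, 4.27 after), so the makeup accounts for part at most and the rest cannot be told apart from other causes with 2 libraries. A difference between cultures was not tested and stays open.

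The longest tRNAs had few reads in cca_exp 1: relative to wt_exp 1 the median log2 ratio of read shares was −4.52 over the 5 tRNAs of 88 nt or more and 0.70 over the 4 of 81 to 87 nt. Spearman's correlation of length with the ratio was −0.92 over the 9 tRNAs longer than 80 nt, which restates the pattern on the tRNAs it was seen in. All 5 of 88 nt or more are serine or selenocysteine tRNAs and no shorter one is, so a loss by length cannot be told apart from a loss of this kind of tRNA. In cca_stat 1 over wt_stat 1 the order did not follow length: tRNA-SeC-TCA (91 nt) was at −4.73, tRNA-Leu-TAA (87 nt) at −3.38 and tRNA-Ser-GCT (93 nt) at −1.24. The cca genotype was argued against as the cause by cca_exp 2, where the same 5 tRNAs had a median of 0.43 relative to wt_exp 3. The 8 shorter tRNAs with tails ending in G were at a median of 0.15. This argues against a poor recovery of such tails as strong as the loss of the longest tRNAs. A weaker one cannot be excluded, since read shares are relative. Reads with a G before the CCA made up 79.4% in wt_exp 1 and 66.3% in cca_exp 1.

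Other splits of the same libraries were fitted with edgeR. For complete ends in cca against wild type over both phases, 3 of 100 splits called at least the 6 tRNAs of the real split, the real one included. That count takes the phases as independent, while same-numbered wild-type libraries, which also share a series, went together across phases. Moved as pairs there are 10 splits, too few for a share under 0.05, of which 2 called at least 6 (the real one included, highest other 16). The highest other of all splits called 16 and set wt_exp 1, wt_exp 2, wt_stat 1 and wt_stat 2 against wt_exp 3, wt_stat 3 and the 4 cca libraries, so that the cca libraries stayed on 1 side, and the cause of its count was not tested. With the library series as a term the real split called 14. For CC among incomplete ends the real split called 0 and 100 of 100 splits called at least as many (highest other 2, and 10 of 10 moved as pairs, highest other 0). Any split reaches a count of 0, so this says nothing on chance. For wt_stat against wt_exp there are 10 splits, too few for a share under 0.05. There the real split called 0 for complete ends (10 of 10 splits called as many, highest other 12, with wt_exp 1, wt_stat 1 and wt_stat 3 against the rest) and 0 for abundance (10 of 10, highest other 0), where again any split reaches 0. The 4 splits that part all 3 same-numbered pairs, the real one included, called 0 for complete ends. The split with 12 keeps the pairs numbered 1 and 2 together. A count that far above the real 0 points to a structure of the samples, whose cause was not tested.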

How the results depend on the processing

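In this part, the fits without both wt_exp 3 and rnt_exp 2, lists by the tail's last base, camera with the series as a term, only CC ends as incomplete, crossed replicate numbers, lists with each library left out, the rRNA operon list less a threonine GGT tRNA, and shares permuted as same-numbered pairs were chosen after seeing the data. Of 2561 alternatives, 615 for counts and shares of a comparison stayed within the limit set and 97 moved. For single tRNAs and other values, 1718 kept direction and side of the threshold, 62 lost the threshold, 10 passed it, 21 moved and 38 reversed. Where no reason is given, the cause was not tested.

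Called tRNAs with lower odds of a complete end went, in cca_stat against wt_stat, from 5 to 14 with the library series as a term, 11 with DESeq2, 8 with only CC, C and no added base as incomplete, 0 with only CC ends, 0 with only the groups compared (fewer libraries for the dispersion) and 0 to 6 with a library left out. Over both phases 6 became 14, 12, 13 and 12 in the first 4 of these, and 0 to 10 with a library left out. In cca_exp against wt_exp, 0 became 1 with the series (tRNA-Cys-GCA) and 1 with DESeq2 (tRNA-Gln-TTG). In rnt_exp against cca_exp, 0 became 1 with only the groups compared (tRNA-Met-CAT-3-1). For CC among incomplete ends in cca, 0 became 1 (tRNA-Cys-GCA) without wt_exp 3 and rnt_exp 2. Abundance calls went from 0 to a range of 0 to 2 with a library left out in cca_exp against wt_exp, rnt_exp against cca_exp, cca_stat against cca_exp and the interaction. The 2 came without cca_exp 2, where the lone cca_exp 1 is assumed to vary like the other groups.

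Outside wt_stat against wt_exp, 2 pairs at most were too few to decide whether replicate numbers pair libraries. Correlations of deviations in log2 odds were 0.37 and 0.05 for cca_exp with wt_exp, −0.36 and −0.34 for cca_stat with wt_stat, −0.47 and −0.57 for rnt_exp with wt_exp, −0.19 for cca_exp with cca_stat and −0.38 for cca_exp with rnt_exp. In log2 CPM they were 0.31 and 0.21, 0.10 and 0.18, −0.61 and −0.68, 0.68, and −0.41 in that order. For groups of 2 both pairs give the same value. Matched by series, rnt_exp with wt_exp had 0.57 and 0.08 in log2 odds and 0.68 and 0.06 in log2 CPM, cca_exp with wt_exp 0.37 and 0.50, and 0.31 and 0.25, and cca_stat with wt_stat −0.36 and −0.05, and 0.10 and −0.09. With the replicate number as a block the count was 2 in cca_exp against wt_exp (tRNA-Gln-TTG and tRNA-Leu-GAG), 15 in cca_stat against wt_stat, 18 over both phases and 1 for CC among incomplete ends (tRNA-Cys-GCA at 3.24, adjusted p = 0.0206 in edgeR). The block left 0 list calls for complete ends in rnt_exp against cca_exp (1 without it) and 2 in rnt_exp against wt_exp (3), and for abundance 1 in cca_stat against wt_stat (2), 2 in cca_exp against wt_exp (3) and 2 in the interaction (3). In wt_stat against wt_exp, where number and series are the same, it changed no call. Crossed numbers gave 0 calls in each of the comparisons they were run on.

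With an estimated correlation, called lists for complete ends went from 2 to 0 in cca_stat against wt_stat, 3 to 0 in rnt_exp against wt_exp, 1 to 0 in rnt_exp against cca_exp, 1 to 0 in wt_stat against wt_exp, 2 to 0 in cca_stat against cca_exp and 2 to 0 in the interaction. For abundance they went from 3 to 1 in cca_exp against wt_exp, 2 to 0 in cca_stat against wt_stat, 2 to 0 in rnt_exp against cca_exp, 3 to 0 in cca_stat against cca_exp and 3 to 0 in the interaction. With the series as a term, list calls for complete ends went from 0 to 1 over both phases, 3 to 1 in rnt_exp against wt_exp and 1 to 0 in rnt_exp against cca_exp, and for abundance from 2 to 0 in cca_stat against wt_stat, 0 to 2 in rnt_exp against wt_exp and 2 to 0 in rnt_exp against cca_exp. With a library left out, list calls for complete ends ranged from 0 to 1 over both phases (0 with all), 1 to 2 in cca_stat against cca_exp (2), 0 to 2 in cca_stat against wt_stat (2), 0 to 3 in rnt_exp against cca_exp (1), 0 to 3 in rnt_exp against wt_exp (3) and 0 to 2 in wt_stat against wt_exp (1), with 2 throughout in the interaction and 0 throughout in cca_exp against wt_exp. For abundance they ranged from 1 to 3 in cca_exp against wt_exp (3), 0 to 3 in cca_stat against cca_exp (3), 0 to 1 in cca_stat against wt_stat (2), 0 to 3 in the interaction (3), 0 to 3 in rnt_exp against cca_exp (2) and 0 to 2 in rnt_exp against wt_exp (0), with 0 throughout in wt_stat against wt_exp. Without cca_exp 1 they fell to 1 in cca_exp against wt_exp and to 0 in cca_stat against cca_exp, rnt_exp against cca_exp and the interaction. The rRNA operon list less either threonine GGT tRNA changed no call. By the tail's last base, complete-end calls went from 0 to 1 over both phases, 1 to 0 in rnt_exp against cca_exp and 1 to 2 in wt_stat against wt_exp.

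Weighting each tRNA alike, which lets rare tRNAs count as much as common ones, moved differences in CC share (percentage points) from 3.84 to 8.13 in cca_stat against wt_stat, −1.23 to −3.65 in wt_stat against wt_exp, −2.46 to −0.312 in cca_stat against cca_exp, −2.33 to −0.188 in rnt_exp against cca_exp, 2.73 to 4.60 in rnt_exp against wt_exp, 5.06 to 4.79 in cca_exp against wt_exp and 4.45 to 6.46 in cca over both phases, where the exact permutation p within phases went from 0.01 to 0.06. For complete ends it moved −5.93 to −4.20 in cca_exp against wt_exp, −3.85 to −8.73 in cca_stat against wt_stat, −3.26 to −7.49 in rnt_exp against wt_exp, 2.68 to −3.29 in rnt_exp against cca_exp, 1.16 to 4.99 in wt_stat against wt_exp and 3.25 to 0.456 in cca_stat against cca_exp, and −4.89 to −6.46 in cca over both phases, where the exact permutation p went from 0.03 to 0.12. Permuted as same-numbered pairs of both phases, no p was under 0.1, the smallest possible. Within series, the CC difference of rnt_exp and cca_exp was 1.33 instead of −2.33. With a library left out, CC differences ranged from 4.45 to 6.26 in cca_exp against wt_exp, 2.88 to 4.79 in cca_stat against wt_stat, 3.97 to 5.05 over both phases, −0.883 to 6.34 in rnt_exp against wt_exp, −5.94 to 1.28 in rnt_exp against cca_exp, −1.84 to −0.0266 in wt_stat against wt_exp and −3.41 to −1.503 in cca_stat against cca_exp. Those of complete ends ranged from −7.27 to −4.92, −6.50 to −1.1995, −6.22 to −3.57, −6.30 to −0.211, −0.369 to 5.72, −0.168 to 2.18 and 0.6001 to 5.90 in the same order. For C they were 0.429 to 0.525, 0.246 to 0.479, 0.361 to 0.478, −0.0210 to 0.0963, −0.498 to −0.381, −0.103 to −0.00880 and −0.277 to −0.0445, and for no added base 0.0777 to 0.155, 0.211 to 0.558, 0.159 to 0.332, −0.0418 to 0.0324, −0.151 to −0.0938, −0.0564 to 0.0178 and 0.0743 to 0.421. For other ends they were −0.209 to 0.611, −2.14 to 0.674, −0.924 to 0.483, −0.0906 to 1.11, −0.383 to 0.815, −0.70004 to 0.909 and −2.29 to 0.527. For CC and complete ends the signs turned without rnt_exp 2 (−0.883), without rnt_exp 1 (1.28 and −0.369) and without wt_exp 3 (−0.168).

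Reversed log2 changes, none of them called, were mostly those of tRNA-Asp-GTC. For complete ends it had 0.0520 (series as a term), 0.72 (only CC, C and no added base) and 0.72 (only CC) in rnt_exp against cca_exp, −0.0688 and −0.204 with the last 2 in the interaction, and −0.10 without wt_exp 3 and rnt_exp 2 in wt_stat against wt_exp. For abundance it had 0.0362 in cca_exp against wt_exp, 0.16 in cca_stat against wt_stat and −0.24 in cca_stat against cca_exp with library totals only. That scaling moved the median of all tRNAs by 0.64, 0.35 and −0.40 in the same order. tRNA-Asp-GTC also had 0.0735 in cca_stat against wt_stat with only complete ends. In rnt_exp against cca_exp it had 0.40 with DESeq2, 0.40 with its size factors and 0.44 without wt_exp 3 and rnt_exp 2. In rnt_exp against wt_exp, abundance of tRNA-Ala-TGC was 0.19 with the series and 0.13 with the replicate block, and pooled tail 1 was −0.17 without wt_exp 3 and rnt_exp 2.

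With a library left out, tRNA-Asp-GTC ranged for complete ends from −1.24 to 0.58 (cca_stat against wt_stat), −0.55 to 0.24 (rnt_exp against cca_exp), −0.20 to 0.67 (wt_stat against wt_exp), −0.29 to 1.53 (cca_stat against cca_exp) and −0.49 to 1.32 (interaction). For CC among incomplete ends in rnt_exp against wt_exp it ranged from −0.56 to 1.28, and tRNA-Leu-TAA from −0.94 to 4.94. For abundance tRNA-Asp-GTC ranged from −1.04 to 0.26 (cca_stat against wt_stat), −0.82 to 0.44 (rnt_exp against cca_exp), −0.64 to 0.18 (wt_stat against wt_exp), −0.79 to 0.68 (cca_stat against cca_exp) and −0.36 to 1.02 (interaction), pooled tail 1 from −0.39 to 1.49 (rnt_exp against wt_exp), and pooled tail 4 from −0.49 to 1.56 (wt_stat against wt_exp) and −2.13 to 0.16 (interaction).

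Changes of named tRNAs that a library left out moved more than 1.5 times in size, with no change of sign, ranged as follows. For complete ends tRNA-Asp-GTC had −0.99 to −0.08 over both phases and −1.14 to −0.35 in cca_exp against wt_exp. In cca_stat against cca_exp tRNA-Gln-TTG had 0.82 to 1.70, tRNA-Ser-CGA 0.72 to 2.77 and tRNA-Ser-GCT 0.66 to 2.48, and tRNA-Leu-TAA had −2.66 to −1.38 in the interaction. tRNA-Met-CAT-3-1 had −2.90 to −0.80 in rnt_exp against cca_exp and −2.93 to −0.84 in rnt_exp against wt_exp, with tRNA-Lys-TTT at −2.41 to −0.79. In wt_stat against wt_exp tRNA-Leu-TAA had 0.71 to 1.98, tRNA-Thr-TGT 1.04 to 2.33 and tRNA-Val-TAC 0.06 to 2.36. For CC among incomplete ends tRNA-Asp-GTC had 0.61 to 1.53 over both phases, and in rnt_exp against wt_exp pooled tail 1 had 0.68 to 3.08 and tRNA-Gly-TCC 0.07 to 3.56. For abundance tRNA-Asp-GTC had −1.07 to −0.54 in cca_exp against wt_exp. In cca_stat against wt_stat tRNA-SeC-TCA had −5.44 to −0.15, tRNA-Asn-GTT −1.46 to −0.36 and pooled tail 3 0.64 to 2.33. In cca_stat against cca_exp tRNA-Leu-CAA had 0.29 to 1.76, tRNA-Ser-CGA 0.49 to 4.75 and tRNA-Ser-TGA 0.64 to 2.83. In the interaction tRNA-Pro-TGG had −1.78 to −0.09 and tRNA-Ser-CGA 0.41 to 4.71. In rnt_exp against cca_exp pooled tail 3 had −2.27 to −0.85 and tRNA-Asn-GTT 0.56 to 2.11. In rnt_exp against wt_exp tRNA-Ala-TGC had −1.88 to −0.11, tRNA-Asp-GTC −1.49 to −0.27 and tRNA-Leu-TAG −1.03 to −0.50, and in wt_stat against wt_exp tRNA-Gly-CCC had 0.59 to 1.195 and tRNA-Leu-TAA 0.96 to 1.68. Depth limits rare tRNAs: tRNA-Met-CAT-3-1 had 188 to 3472 reads per library and tRNA-Arg-CCT 334 to 6308. tRNA-SeC-TCA had 165 reads in cca_exp 1, where the longest tRNAs had few reads, and 59094 in its deepest library.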

Other observations

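All values in this part were chosen after the data were seen. The profile of CC shares over tRNAs in wt_exp 1 was closer to the cca libraries (Spearman 0.89 to 0.92 over 44 tRNAs) than to wt_exp 2 and wt_exp 3 (0.75 and 0.74), while wt_exp 3 and wt_stat 3 were at 0.99.

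Ends outside CCA, CC, C and no added base averaged 13.3% over tRNAs in rnt_exp 1, against 1.501% to 7.21% in the other 11 libraries (4.14% in rnt_exp 2). Pooled over reads rnt_exp 1 did not stand apart, at 4.20% against 1.09% (cca_stat 1) to 4.93% (wt_stat 3) in the others. In rnt_exp 1 they made up 66.2% of the 399 reads of tRNA-Met-CAT-3-1, 47.9% of the 3287 reads of tRNA-Val-GAC-1-1 and 36.4% of the 7274 reads of tRNA-Gly-TCC, the highest shares among the 44 tested tRNAs, named after their values were seen. The end CCACC in wt_exp 3 had 1928 reads in tRNA-Asp-GTC, 343 in tRNA-Val-TAC and 301 in tRNA-Cys-GCA.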
